A study of Homo sapiens with 10 samples.

How the data were processed

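The series holds 10 samples in 8 groups, all from Huh7, an established human liver cancer cell line. RNA-seq libraries came from cells transfected with a control siRNA (siNC) or an siRNA against the RNA helicase DHX37 (siDHX37), with 2 libraries per group. ChIP-seq, which maps DNA carrying a given chromatin mark, was run for H3K27ac (histone H3 acetylated at lysine 27, a mark of active promoters and enhancers) with 1 library per siRNA. CUT&Tag, which tags DNA near an antibody-bound protein, was run with an anti-Flag antibody in cells carrying Flag-DHX37 from a lentivirus and with an anti-PLRG1 antibody in untreated cells, with 1 library each. The 2 ChIP input samples were not used here. No CUT&Tag control library was used here.

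For RNA, the authors' deposited table gives whole-number read counts per gene and library. The same table holds the authors' own log2 fold changes, p-values and false discovery rates, which were used only where a sentence names that table. An Illumina mRNA kit with paired-end sequencing was used for RNA, per the labels' protocols. The RNA aligner, counter, gene annotation and strand setting are not given in the sources used here, so a gene and an overlapping or antisense neighbour may share reads. The total count per library ranged from 9586863 to 18379839. Each of the 17004 gene names in the table had at least 10 reads over the 4 libraries. Of these names, 15674 matched a current symbol or synonym in the reference gene table, 1321 did not, and 9 were dates written in place of a gene symbol; unmatched and date names stayed in the tests but were not named.

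For ChIP-seq and CUT&Tag, each deposited list gives summits 1 bp long with a −log10 score per summit, called separately for each library. Per the submitters' processing notes, the build was hg38 and the tools were Bowtie, Picard, deepTools and MACS2, with no versions or thresholds. Whether the authors' −log10 scores come from a p-value or a q-value, and whether the inputs were used, is not given in the sources used here. Scores were used to rank, filter and sum summits within their own list. For named regions the share of the list's total score was also set beside that of the other list, as a description with no test. Summits on chromosomes 1 to 22, X and Y were used. The reference gene table, on the same build, gives the start and end of each gene without strand, so a transcription start could not be told from the other gene end. Every analysis that was set up for transcription start sites therefore used either annotated gene end. No read depth comes with the summit lists, so depth differences between those libraries are unknown.

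Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg over all tested genes, threshold 0.05). Levels are TMM-scaled counts per library total (CPM). Replicates carry the numbers 1 and 2 in both groups, and the labels do not say what the numbers share, so the fit had no block. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Estimated correlation and fry were alternatives. The form with an estimated correlation rests on the few residual degrees of freedom of 4 libraries and has little power. A list that does not pass there is not thereby shown to rest on correlated genes. DESeq2 1.42.0 was an alternative for genes. On simulated counts with 200 changed genes, drawn from the means of this comparison, edgeR recovered 67.0% of changes of 0.5 and 87.8% of changes of 1 on the log2 scale, over 14489 genes, and 3.82% of its calls were false. DESeq2 recovered 49.5% and 75.5% of the same genes with 0 false calls. On simulated values for 14727 genes, camera called 5 of 5 shifted lists and 0 of 33 unshifted lists. The simulated genes were drawn independently, while the G1/S list had an estimated correlation of 0.357. The simulation therefore does not measure false calls among lists of correlated genes.

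Positions were analysed in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and drawn with matplotlib 3.10.9. Summits within 500 bp were called shared, and shares carry exact Clopper-Pearson 95% intervals that cover counting error only. Chance levels came from 1000 circular shifts of a list within each chromosome (one-sided) and from 1000 draws of H3K27ac summits with the same share near a gene end. Super-enhancers, clusters of enhancers with high total signal, were rebuilt from the summits as an approximation: summits within 2.5 kb of a gene end were left out, the rest were stitched across gaps of up to 12.5 kb, regions were ranked by summed score, and regions past the point of slope 1 of the curve scaled to its highest region were called. Binding in super-enhancers and in other stitched regions was compared with Fisher's exact test, and again over 10 length bins with a Cochran-Mantel-Haenszel test. The list of super-enhancers was shifted 100 times for its chance level. Genes with a summit within 1 kb of either end, and the nearest expressed genes of super-enhancers, were compared with 10000 draws of other expressed genes from the same of 10 expression groups (two-sided permutation, adjusted over 11 classes). Genes and regions are not independent replicates, so these p-values describe the libraries used.

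The named genes followed a rule set before the data were examined. They are DHX37, DHX34, PLRG1 and CCND1; the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping libraries and a mean of at least 100 counts in a group; up to 4 members of each list with the smallest adjusted p among those past the threshold (or the 2 most abundant where none passed); the nearest genes of the 5 highest super-enhancers in siNC and of the 5 largest falls and rises in score share; the 10 genes with a DHX37 and a PLRG1 summit at an end and the best worse rank; and all summits within 100 kb of CCND1. Some genes that this rule selects are not reported here. The same rule fixed 38 gene lists: DEAH-box helicases related to DHX37, G1/S cyclins with RB-E2F, DNA replication, G2/M and mitosis, CDK inhibitors, p53 targets, 40S and 60S ribosomal proteins, small subunit processome, 60S biogenesis, RNA polymerase I, PRP19 complex, spliceosome core, snoRNA hosts, hepatocyte secreted proteins, hepatocyte metabolism, liver transcription factors, cholesterol synthesis, fatty acid synthesis, glycolysis, hypoxia, integrated stress response, ER chaperones, heat shock, interferon, NF-kB, immediate early genes, apoptosis, mesenchymal transition, Wnt and YAP targets, enhancer machinery, nonsense-mediated decay, oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and stromal, endothelial and blood, and cholangiocyte and other epithelial markers.

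The alternatives were, for RNA, DESeq2 size factors, library totals, DESeq2, no count filter, stricter thresholds, the replicate number as a block and leaving out each library. For summits they were distances of 200 and 1000 bp, a score of at least 10 and equal list sizes. For super-enhancers they were 5 kb stitching, all summits kept, protein-coding gene ends only, ranking by number of summits, the top 500 regions and leaving out the highest regions. For binding and expression they were gene ends within 5 kb, unmatched genes, genes with H3K27ac at an end and genes within 50 kb.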

Results

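The study asked, by its title and design, which genes depend on DHX37 in liver cancer cells and whether DHX37 and its partner PLRG1 act at super-enhancers, with cyclin D1 (CCND1) as the named target. The data comprised 4 RNA-seq libraries, 2 with siNC and 2 with siDHX37, an H3K27ac summit list for each siRNA, and CUT&Tag summit lists for Flag-DHX37 and for PLRG1. RNA totals were 15348027 and 17374623 counts for siNC replicates 1 and 2, and 18379839 and 9586863 for siDHX37 replicates 1 and 2. The lists held 57944 (siNC) and 58505 (siDHX37) H3K27ac summits, 10218 DHX37 summits and 7709 PLRG1 summits on the primary chromosomes. The labels do not say whether the RNA libraries came from separate cultures, so p-values measure only the spread between these libraries. Each summit list is 1 library with no replicate.

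DHX37 RNA fell to 0.307 of its control level with siDHX37. It measured 35.2 ± 3.36 CPM with siNC and 10.7 ± 0.398 CPM with siDHX37 (SD, n = 2 each), a log2 fold change of -1.70 (SE 0.10; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.64e-50). CCND1, which encodes cyclin D1, the partner of CDK4 and CDK6 in G1, fell from 482 ± 23.5 to 93.3 ± 4.06 CPM (SD, n = 2 each), a log2 fold change of -2.36 (SE 0.04; edgeR, adjusted p = 7.86e-228). DHX34, a related helicase, rose by 0.21 on the log2 scale (SE 0.06; edgeR, adjusted p = 0.000813), a call lost without siNC replicate 2 (adjusted p = 0.0730). PLRG1 was at 107 ± 2.41 and 116 ± 2.08 CPM (SD, n = 2 each), a log2 difference of 0.12 (SE 0.05; edgeR, adjusted p = 0.0308). That PLRG1 call was lost with DESeq2 (adjusted p = 0.167) and without siDHX37 replicate 1 or either siNC replicate in edgeR (adjusted p from 0.0932 to 0.274), and the authors' deposited table gives it a false discovery rate of 0.204. DHX37 lies at chromosome 12, 124946826 to 124989131, and CCND1 at chromosome 11, 69641156 to 69654474 (hg38). The description of siDHX37 replicate 1 names DHX34 as the siRNA target while its title names DHX37; in that library DHX37 was at 0.313 and DHX34 at 1.13 times the siNC mean.

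**Figure D1:**
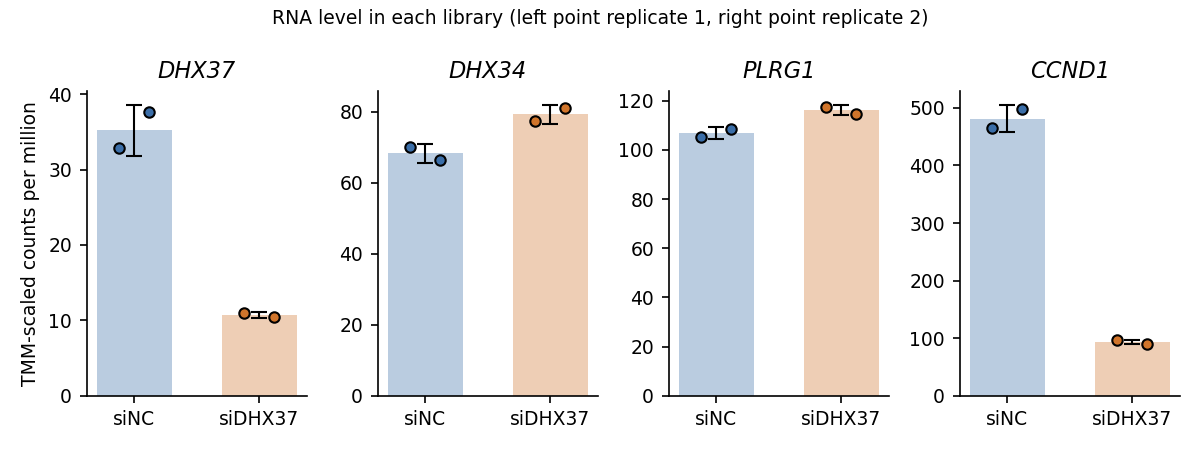
RNA level of DHX37, DHX34, PLRG1 and CCND1 in TMM-scaled counts per library total (vertical axes, from 0, a scale per gene) for siNC and siDHX37; bars are means, error bars SD, points the 2 libraries of each group. DHX37 and CCND1 lie lower in both siDHX37 libraries, at means of 10.7 and 93.3 CPM.

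Across the transcriptome, 3415 genes rose and 3680 fell of 14727 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, threshold 0.05). At least a 2-fold change was reached by 418 of the higher and 389 of the lower genes. Among genes past the threshold with a mean of at least 100 counts in a group and non-overlapping libraries, the largest falls beside CCND1 were in LRRC3DN (-3.89), LRRC3 (-3.81), CDKN1C (-3.33), EIF4EBP1 (-2.75), AGFG1 (-2.65), TTC7B (-2.62), ESPN (-2.44), NACC2 (-2.43) and TIMM17A (-2.40), given as log2 fold changes. CDKN1C encodes the CDK inhibitor p57 and EIF4EBP1 a repressor of cap-dependent translation. EIF4EBP1 went from 85.6 to 12.4 CPM (SE of the log2 fold change 0.08), and AGFG1 from 252 to 40.9 CPM (SE 0.05). CDKN1C had -2.47 without siDHX37 replicate 1 and -4.19 without siDHX37 replicate 2, and LRRC3 had -4.51 without siDHX37 replicate 1. LRRC3DN and LRRC3 share a locus name and could share reads, so they are uncertain as separate genes. Under the same conditions the largest rises were in MAB21L2 (2.21), B3GALT2 (2.20), NAV3 (2.04), ZDHHC8P1 (1.93, a pseudogene and so uncertain), C9orf172 (1.91), CDKN2B (1.91), DGKK (1.84), RASSF5 (1.83), SSTR2 (1.78) and GABRG1 (1.78). CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, went from 21.3 to 79.9 CPM (SE 0.07). Among the 6160 genes past the threshold with a mean of at least 100 counts in a group, 37 fell by more than DHX37 itself, CCND1 included. Off-target effects of the siRNA were not tested here, because its sequence is not given in the sources used here, so these are changes with siDHX37 and could include genes that do not depend on DHX37. The authors' deposited table calls 4294 genes, 1929 higher and 2365 lower, and the test above called all 4294 in the same direction plus 2801 more. DESeq2 on the same counts called 2021 higher and 2379 lower genes.

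Cell cycle genes were lower with siDHX37. Of 39 DNA replication genes, 36 fell, 1 rose and 2 did not pass (median log2 fold change -0.45; camera, adjusted p = 3.5e-15). That list's adjusted p was 0.514 with an estimated correlation. The helicase subunits MCM7 (-0.71), MCM4 (-0.75), MCM6 (-0.92) and MCM2 (-0.70) were among them. Of 35 G2/M and mitosis genes, 29 fell, 2 rose and 4 did not pass (median -0.35; camera, adjusted p = 5.4e-11; adjusted p = 0.514 with an estimated correlation). KIF23 (-1.03), ANLN (-0.58) and the proliferation marker MKI67 (-0.51) fell, while the kinetochore motor CENPE rose (1.14). Of 21 tested G1/S genes, 13 fell, 3 rose and 5 did not pass (median -0.29; camera, adjusted p = 5.6e-05; adjusted p = 0.583 with an estimated correlation). Beside CCND1, CCNE1 (-1.38), E2F1 (-0.86) and MYBL2 (-0.69) fell. CDK inhibitors went both ways, with CDKN2B higher and CDKN1C and CDKN1B (-0.45) lower among 7 members, 2 rising, 2 falling and 3 not past (camera, adjusted p = 0.738); CDKN2A counted as the other riser (0.17), a call lost without siDHX37 replicate 1 (adjusted p = 0.225), without siNC replicate 1 (0.336) and with DESeq2 (0.129). Of 23 p53 targets, 10 fell, among them MDM2 (-0.47) and CCNG1 (-0.48), and 3 rose, among them SESN2 (0.96) and XPC (0.40), while 10 did not pass (camera, adjusted p = 0.427).

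**Figure D2:**
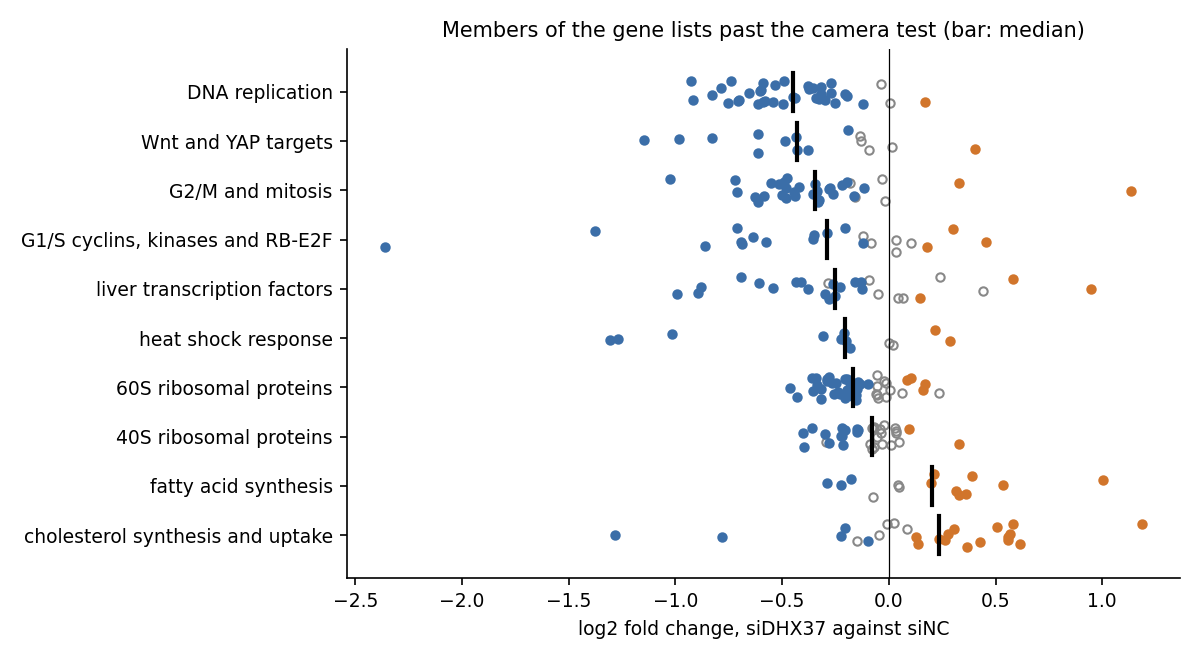
Log2 fold change of siDHX37 against siNC (horizontal axis) for each tested member of the 10 gene lists past the camera test; blue points fell and orange points rose past the edgeR threshold, open grey points did not pass, and vertical bars are list medians. DNA replication has a median of -0.45 and cholesterol synthesis one of 0.24. None of the 10 lists passes with an estimated correlation, a form with little power at 4 libraries.

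Ribosomal protein genes were modestly lower. Of 46 genes for 60S proteins, 31 fell, 4 rose and 11 did not pass (median -0.17; camera, adjusted p = 8.0e-05; adjusted p = 0.583 with an estimated correlation), with RPL23 (-0.46), RPL15 (-0.36), RPL3 (-0.32) and RPL26 (-0.34) as examples. Of 32 genes for 40S proteins, 13 fell, 2 rose and 17 did not pass (median -0.08; camera, adjusted p = 0.0139; adjusted p = 0.660 with an estimated correlation), with RPS18 (-0.40) and RPS16 (-0.36) lower. Without siDHX37 replicate 2 or siNC replicate 1 the 40S list no longer passed (camera, adjusted p = 0.0556 and 0.143). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. DHX37 is known for work in the small subunit processome, which builds the 40S subunit; of 46 tested genes of that machinery 17 fell, 5 rose and 24 did not pass (camera, adjusted p = 0.146), with NHP2L1 (-0.63), NOP56 (-0.37), NOP58 (-0.36) and DIEXF (-0.73) lower. Of 35 genes of 60S biogenesis, 10 fell, LYAR (-0.42) and NOP2 (-0.28) included, 5 rose, NOC2L (0.29) included, and 20 did not pass (camera, adjusted p = 0.615). RNA polymerase I genes had 6 of 17 lower, nucleolin NCL (-0.31) and NPM1 (-0.19) included, 2 higher and 9 not past (camera, adjusted p = 0.386). Of 16 snoRNA host genes, 6 fell, SNHG15 (-0.56) and SNHG1 (-0.30) included, 4 rose, SNHG3 (0.60) included, and 6 did not pass (camera, adjusted p = 0.676).

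Splicing and RNA helicase genes shifted in both directions. Of 31 core spliceosome genes 16 fell, 4 rose and 11 did not pass (camera, adjusted p = 0.0627); SF3B3 (-0.48) and SNRPD3 (-0.41) fell and SF3B2 (0.62) rose. In the PRP19 complex, to which PLRG1 belongs, 5 of 19 genes fell, CWC22 (-0.32) and PPIL1 (-0.32) included, 3 rose, ISY1 (0.73) included, and 11 did not pass (camera, adjusted p = 0.738). Of 15 DEAH-box helicase genes, 6 fell, 1 rose and 8 did not pass (camera, adjusted p = 0.194), and beside DHX37 the fallers included DHX33 (-0.33), DHX9 (-0.28) and DHX15 (-0.25). Of 15 nonsense-mediated decay factors, 7 fell, CASC3 (-0.81) and MAGOH (-0.42) included, 2 rose and 6 did not pass (camera, adjusted p = 0.302). The enhancer machinery list held coactivators and kinases together with histone deacetylases and other regulators. It had 7 of 29 genes higher, the histone deacetylase gene HDAC1 (0.93), CDK8 (1.31) and HEXIM1 (0.65) included, 8 lower, SMARCC1 (-0.30) included, and 14 not past (camera, adjusted p = 0.506).

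Liver transcription factor genes were mostly lower, and genes of cholesterol and fatty acid synthesis mostly higher. Of 27 liver transcription factor genes 17 fell, 3 rose and 7 did not pass (median -0.25; camera, adjusted p = 0.00154; adjusted p = 0.549 with an estimated correlation), and HNF4A (-0.90), CREB3L3 (-0.99), GATA6 (-0.88) and ONECUT1 (-0.69) fell. Of 25 cholesterol synthesis and uptake genes 15 rose, 5 fell and 5 did not pass (median 0.24; camera, adjusted p = 0.00139; adjusted p = 0.514 with an estimated correlation). HMGCS1 (0.58), INSIG1 (0.61) and TM7SF2 (1.19) rose; INSIG1 encodes a sterol-regulated brake on the pathway. Of 14 fatty acid synthesis genes 8 rose, 3 fell and 3 did not pass (median 0.20; camera, adjusted p = 0.0206; adjusted p = 0.583 with an estimated correlation), with ME1 (1.00), ACSL3 (0.53), FADS2 (0.31) and ELOVL6 (0.36) higher. Among 31 hepatocyte secreted proteins 12 fell, FGA (-0.84), FGG (-0.59) and APOA1 (-0.89) included, 8 rose, APOB (0.53) included, and 11 did not pass (camera, adjusted p = 0.436). Of 11 tested hepatocyte metabolism genes 3 fell, GLUL (-0.49) and CYP27A1 (-1.14) included, 3 rose, TAT (1.44) included, and 5 did not pass (camera, adjusted p = 0.615). Glycolysis had 6 of 17 genes higher, PFKM (0.80) and PKM (0.33) included, 6 lower, LDHA (-0.64) included, and 5 not past (camera, adjusted p = 0.429). Of 12 tested hypoxia genes 4 fell, PDK1 (-0.96) included, 3 rose, ADM (0.58) included, and 5 did not pass (camera, adjusted p = 0.738). Of 38 nuclear genes for oxidative phosphorylation 10 rose, SDHB (0.60) included, 7 fell, COX7C (-0.34) included, and 21 did not pass (camera, adjusted p = 0.533). Of the 13 mitochondrially encoded genes 0 are named in the table, so that list was not analysed here.

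Stress and signalling lists were mixed apart from heat shock and the Wnt and YAP targets. Of 12 heat shock genes 8 fell, 2 rose and 2 did not pass (median -0.21; camera, adjusted p = 0.000460; adjusted p = 0.514 with an estimated correlation); HSPA1A (-1.31) and HSPA1B (-1.27), near-identical copies and so uncertain as separate genes, fell with DNAJB1 (-1.02). Of 15 Wnt and YAP target genes 10 fell, 1 rose and 4 did not pass (median -0.43; camera, adjusted p = 0.000321; adjusted p = 0.583 with an estimated correlation); LGR5 (-1.15), ANKRD1 (-0.83) and AJUBA (-0.62) fell. In the integrated stress response 13 of 22 genes fell, SLC7A5 (-0.98), PHGDH (-0.99) and MTHFD2 (-0.74) included, 6 rose, TRIB3 (1.28) included, and 3 did not pass (camera, adjusted p = 0.135). Of 18 ER chaperone genes 6 rose, CRELD2 (0.73) and CALR (0.26) included, 2 fell, XBP1 (-0.23) and HERPUD1 (-0.41), and 10 did not pass (camera, adjusted p = 0.302). Immediate early genes had 8 of 18 higher, DUSP6 (1.09), DUSP5 (1.07) and KLF2 (0.82) included, 7 lower, DUSP1 (-0.71) included, and 3 not past (camera, adjusted p = 0.219). Apoptosis genes had 7 of 19 lower, BCL2L11 (-0.88) and CYCS (-0.65) included, 6 higher and 6 not past (camera, adjusted p = 0.753). Of 17 tested interferon genes 3 fell, 3 rose and 11 did not pass (camera, adjusted p = 0.909). Of 14 tested NF-kB genes 4 rose, ICAM1 (0.69) and NFKB2 (0.67) included, 4 fell, TNFAIP3 (-1.06) and SOD2 (-0.78) included, and 6 did not pass (camera, adjusted p = 0.909). Of 18 tested mesenchymal and matrix genes 7 fell and 5 rose, ITGA5 (0.82), TGFB1 (0.40) and CTGF (0.40) included, and 6 did not pass (camera, adjusted p = 0.722). In the NF-kB and mesenchymal lists the median and the mean were negative while the direction of the camera test was up.

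Markers of other cells and of RNA selection were read as controls. Of 7 tested stromal markers 5 rose, 1 fell and 1 did not pass (median 0.48; camera, adjusted p = 0.194), with COL3A1 (2.37, from 0.631 to 3.16 CPM), LUM (0.74) and PDGFRA (0.48) higher and TAGLN (-0.51) lower. Of 4 tested endothelial and blood markers 0 rose, PECAM1 fell (-0.38; edgeR, adjusted p = 0.000801) and 3 did not pass (camera, adjusted p = 0.610). Of 7 tested cholangiocyte and other epithelial markers 3 fell, SOX9 (-1.13) and KRT19 (-0.37) included, 2 rose and 2 did not pass (camera, adjusted p = 0.194). Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, had 6 of 11 higher, HIST1H2BD (1.42) included, 1 lower, HIST1H2BK (-0.36), and 4 not past (camera, adjusted p = 0.160). Counts adjusted over the list alone were the same as over all genes except for 14 lower G1/S genes, 5 lower DEAH-box helicases, 18 lower processome genes, 5 higher snoRNA hosts, 10 higher secreted proteins and 4 lower fatty acid genes.

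H3K27ac summits were compared between siNC and siDHX37 cells to see how far the active chromatin maps coincide. Of the siNC summits, 66.9% (95% interval 66.5 to 67.3) lay within 500 bp of a siDHX37 summit, and 70.5% (70.1 to 70.8) of the siDHX37 summits lay within 500 bp of a siNC summit. Near a gene end lay 25.1% of siNC and 26.2% of siDHX37 summits, against 6.33% for both lists after circular shifts. With 1 library per group there was no test of a difference between the lists.

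Around CCND1 the H3K27ac list of siNC cells held 13 summits within 100 kb and that of siDHX37 cells 14. None lay inside the gene, which spans chromosome 11, 69641156 to 69654474. Flag-DHX37 had 5 summits there and PLRG1 had 3. The DHX37 scores ran from 7.54 to 11.97, against a list median of 11.41. The PLRG1 scores ran from 8.05 to 12.31, against a list median of 11.38. The DHX37 summits at 69639250, 69655176 and 69700780 and the PLRG1 summit at 69706093 lay below the score minimum of 10 used as an alternative. DHX37 summits at 69639250, 69675654 and 69706278 lay beside PLRG1 summits at 69639374, 69675417 and 69706093, which are 1782 bp below the lower gene end and 20943 and 51619 bp above the higher one. The other DHX37 summits were at 69655176, 702 bp above the higher gene end, and at 69700780. A stitched H3K27ac region at 69687855 to 69709386 was called a super-enhancer in siNC cells, with 4 summits and a summed score of 184.9 against that list's cutoff of 138.7. The matching siDHX37 region, 69687863 to 69709099, held 5 summits and scored 150.6 against its own cutoff of 158.5, so it was not called. That difference in call rests on the cutoff: the region was called in both lists when all summits were kept or when the 1 highest region of each list was left out, and in neither with 5 kb stitching, ranking by number of summits or the top 500 regions. With only protein-coding gene ends left out, it stayed called with siNC and not with siDHX37.

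**Figure D3:**
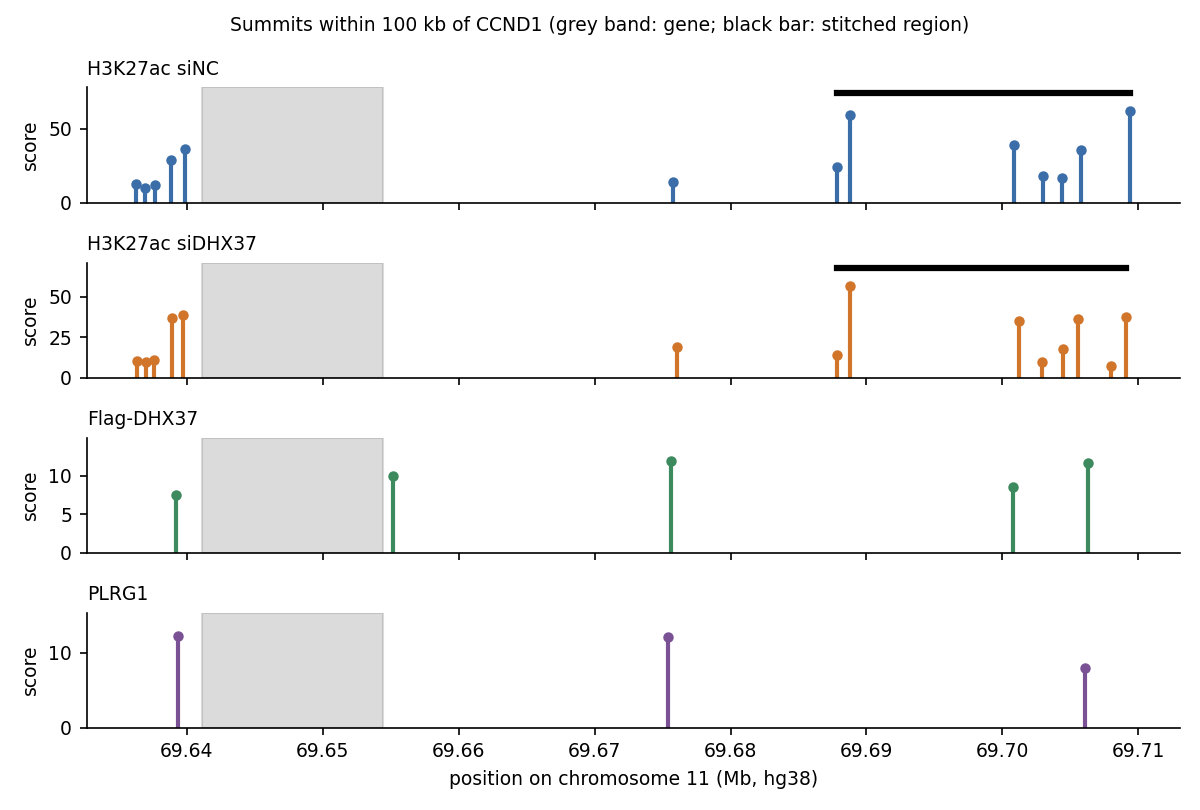
Summits within 100 kb of CCND1 on chromosome 11 (horizontal axis, position in Mb, hg38) with their score in each list (vertical axes, the authors' −log10 values, a scale per list); the grey band is the gene and black bars the stitched region. H3K27ac holds 13 summits with siNC and 14 with siDHX37, and DHX37 and PLRG1 hold 5 and 3.

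Super-enhancers rebuilt from the summits numbered 1306 of 16384 stitched regions with siNC and 901 of 14821 with siDHX37. The highest siNC regions lay nearest to DIP2B, GPR126, RAB8B, FILIP1L and the liver cancer antigen gene GPC3; RNA of RAB8B fell (-0.53), RNA of GPR126 (0.24), FILIP1L (0.46) and GPC3 (0.28) rose, and DIP2B had 0.11, a call lost with DESeq2 and without siDHX37 replicate 2 or either siNC replicate (edgeR, adjusted p of up to 0.204). Of siNC super-enhancers 55.3% (95% interval 52.5 to 58.0) overlapped one called with siDHX37, and 79.6% (76.8 to 82.2) of those called with siDHX37 overlapped one of siNC. In the union of 1477 regions, 709 were called in both lists, 584 with siNC only and 184 with siDHX37 only. All 584 regions called with siNC only held siDHX37 summits inside or within 500 bp. Their summed siDHX37 scores were not all below that list's cutoff of 158.5. The region near FAM35BP summed to 267.2 with siDHX37 and was not called there. In the other direction, the BCL3 region summed to 194.7 with siNC, above the cutoff of 138.7, without a call. A missing call is therefore not always a score below the cutoff. Of the siNC super-enhancers, 18 overlapped no stitched siDHX37 region. By absolute difference, the share of a list's summed score fell most near FILIP1L, from 827 to 569 parts per 1e+06, and then near LOC399900, USP12, PLCB1 and FAM35BP. It rose most at MAN1A1, from 563 to 1242 parts per 1e+06, and then at NRP1, BCL3, the TGF-beta receptor gene TGFBR2 and PTPRK. RNA did not follow these shares in one direction. Where the share fell, FILIP1L (0.46) and PLCB1 (0.22) rose, FAM35BP (-1.17) and USP12 (-0.15) fell, and LOC399900 did not pass (0.29). PLCB1 and USP12, the nearest expressed genes, lay 182479 and 74273 bp from their regions, beyond the 50 kb of the gene window alternative. Where it rose, NRP1 (0.41) and TGFBR2 (0.50) rose, PTPRK (-0.54) and BCL3 (-0.24) fell, and MAN1A1 did not pass (-0.02, SE 0.04). The FAM35BP and BCL3 calls were lost with DESeq2 (adjusted p = 0.062 and 0.058), and the USP12 call under most alternatives, without siDHX37 replicate 1 (edgeR, adjusted p = 0.326) and siNC replicate 2 (0.679) included. FAM35BP had -1.76 without siDHX37 replicate 1 and is a pseudogene, so it is uncertain. The number called depended on the highest regions, which set the scale of the cutoff: leaving out the 1, 2, 5, 20, 50 or 100 highest regions of each list gave more with siNC than with siDHX37 each time (1306 and 1029, 1419 and 1028, 1563 and 1249, 1853 and 1670, 2427 and 2201, 2704 and 2373). Leaving out the 10 highest, the only number tried that turned the order, gave 1558 with siNC and 1623 with siDHX37. These alternatives were added after seeing the data, and the numbers other than 10 after the result for 10.

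**Figure D4:**
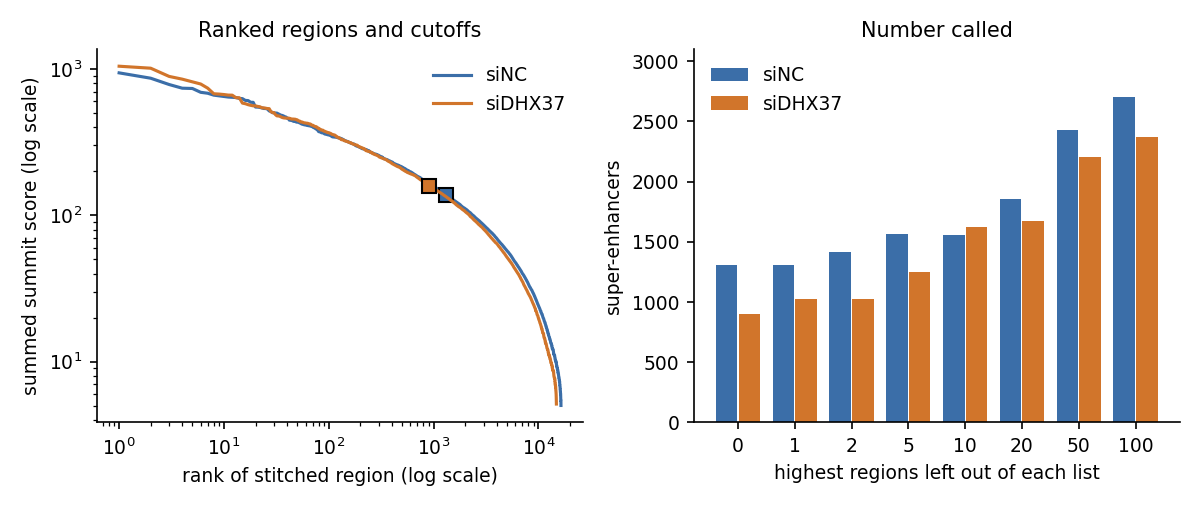
Left, summed summit score of stitched H3K27ac regions by rank (both axes on a log scale), with squares at the cutoff of each list; right, super-enhancers called (vertical axis) when 0 to 100 of the highest regions of each list are left out (horizontal axis). With all regions 1306 are called with siNC and 901 with siDHX37, and without the 10 highest 1558 and 1623.

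DHX37 and PLRG1 summits largely coincided. Of DHX37 summits 57.0% (95% interval 56.0 to 58.0) lay within 500 bp of a PLRG1 summit, and of PLRG1 summits 75.9% (74.9 to 76.8) lay within 500 bp of a DHX37 summit. Circular shifts gave 0.319% and 0.421% (one-sided permutation p = 0.001 for both, the smallest that 1000 shifts can give), and H3K27ac summits drawn with the same share at gene ends gave 19.8% and 24.7%. Gene ends lay within 1 kb of 58.4% of DHX37 and 69.5% of PLRG1 summits, against 6.95% and 6.98% after shifts. H3K27ac summits of siNC cells lay within 500 bp of 52.3% of DHX37 and 63.6% of PLRG1 summits, against 1.80% and 1.83% after shifts (one-sided permutation p = 0.001 for both, the smallest that 1000 shifts can give). The share of DHX37 summits near a PLRG1 summit was 77.5% at gene ends with H3K27ac, 61.5% at gene ends without it, 55.9% at H3K27ac away from gene ends and 25.6% at neither. The 10 genes with the best-ranked pair of summits at an end were SPATC1L, LINC00094, FARP2, MTND1P23, MTND2P28, FAM86C2P, FAM86JP, ZDHHC5, FAM86HP and RALY, of which the MTND copies of mitochondrial sequence and the FAM86 family are multi-copy and so uncertain. RNA of SPATC1L (0.66), FAM86C2P (0.69) and ZDHHC5 (0.16) rose, and that of MTND2P28 fell (-0.087; edgeR, adjusted p = 0.0397). The others did not pass.

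**Figure D5:**
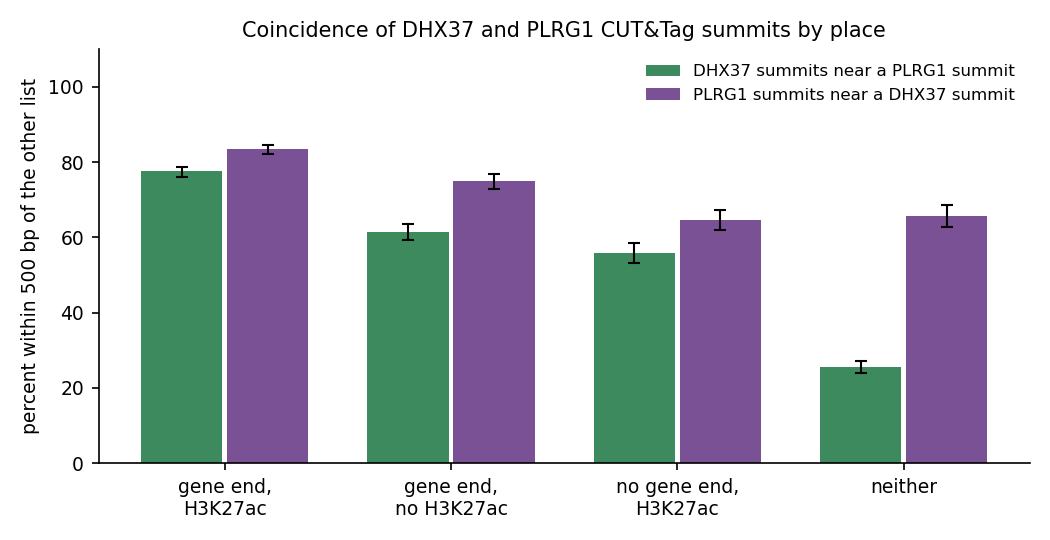
Percent of DHX37 summits within 500 bp of a PLRG1 summit and of PLRG1 summits within 500 bp of a DHX37 summit (vertical axis), by nearness to a gene end and to H3K27ac of siNC cells (horizontal axis); error bars are exact 95% intervals for counting error. The DHX37 share runs from 77.5% at gene ends with H3K27ac to 25.6% at neither.

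Super-enhancers of siNC cells held DHX37 and PLRG1 summits more often than other stitched regions. The regions were not matched on H3K27ac score, by which super-enhancers are chosen. At siNC H3K27ac summits away from gene ends, DHX37 shares ran from 0.714% in the lowest of 10 score groups to 10.6% in the highest. The PLRG1 shares ran from 0.898% to 8.43%. A preference for super-enhancers beyond H3K27ac score was therefore not tested. A DHX37 summit lay in 25.5% of super-enhancers (95% interval 23.2 to 28.0) and in 6.94% of the other regions, an odds ratio of 4.59 (Fisher's exact test over regions, p = 5.62e-85). A PLRG1 summit lay in 20.8% (18.7 to 23.1) and 6.06%, an odds ratio of 4.08 (Fisher's exact test, p = 4.95e-63). Super-enhancers are longer, and per kb they held fewer summits than the other regions, 0.0149 against 0.0223 for DHX37 and 0.0118 against 0.0194 for PLRG1. With all summits kept the odds ratios were 2.831 for DHX37 and 2.497 for PLRG1, and 1.44 (95% interval 1.248 to 1.66) and 1.31 (1.13 to 1.51) when also matched on length. With regions compared within length bins in the first setting the odds ratios were 1.92 (95% interval 1.58 to 2.34) for DHX37 and 1.83 (1.48 to 2.26) for PLRG1. Shares averaged over these bins were 23.7% against 16.3% for DHX37 and 19.6% against 15.7% for PLRG1. With only CUT&Tag summits scoring at least 10, they were 13.2% against 9.05% for DHX37, with an odds ratio within bins of 1.89. For PLRG1 they were then 9.79% against 9.94%, which is no excess, although the odds ratio within bins was 1.49. The bins followed super-enhancer lengths and kept 15075 of 15078 other regions and 1175 of 1306 super-enhancers. Nearly all shorter regions thus stayed in, and length was matched only coarsely. Circular shifts of the lists gave 5.63% and 4.58% of super-enhancers with a summit (one-sided permutation p = 0.0099 for both, the smallest that 100 shifts can give). A DHX37 summit lay in 20.9% of regions called with siNC only, 31.7% of those called in both lists and 23.9% of those called with siDHX37 only. Per kb these classes held 0.0145, 0.0143 and 0.0165 DHX37 summits. DHX37 summits were thus not more frequent where the call was lost with siDHX37.

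Genes bound by DHX37 or PLRG1 at an end did not fall as a group by their median. Among 13849 expressed genes with coordinates, 5800 had a DHX37 summit at an end, 5336 a PLRG1 summit, 4482 both and 7195 neither. CCND1 has a DHX37 summit within 1 kb of its higher end and no PLRG1 summit within 1 kb of either. Of genes with both summits 1195 rose (26.7%) and 1260 fell (28.1%), against 21.4% and 24.4% of genes with neither summit, unmatched on expression. With library totals 1396 rose and 1060 fell. The median log2 fold change of genes with both summits lay 0.033 above that of drawn unbound genes of like expression (permutation, adjusted p = 0.000183, raw p = 0.0001, the smallest that 10000 draws can give). The differences were 0.028 for all DHX37-bound and 0.030 for all PLRG1-bound genes (permutation, adjusted p = 0.000183 for both). Unmatched on expression, they were 0.012 for DHX37, no longer past the threshold (permutation, adjusted p = 0.0729), 0.015 for PLRG1 and 0.017 for both summits (permutation, adjusted p = 0.0459 and 0.0375). Genes with only a DHX37 or only a PLRG1 summit did not differ past the threshold (0.0085 and 0.0098; permutation, adjusted p = 0.539 for both). When only genes with H3K27ac at an end were compared, the differences for all DHX37-bound, all PLRG1-bound and doubly bound genes were 0.0041, 0.0062 and 0.0085, none past the threshold (permutation, adjusted p from 0.461 to 0.481).

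Genes nearest to super-enhancers were compared in the same way to ask whether loss of a call went with loss of RNA. Nearest genes of regions called with siDHX37 only had 71 rises and 39 falls among 176, and a median of 0.11, which was 0.13 above drawn genes (permutation, adjusted p = 0.000183, again from the smallest possible raw p). Nearest genes of regions called in both lists lay 0.067 above drawn genes (adjusted p = 0.000183 by permutation), a call lost with all genes within 50 kb (0.029, adjusted p = 0.0830); without siNC replicate 1 the difference was 0.036 (adjusted p = 0.0378). Nearest genes of regions called with siNC only, 533 in number, had 155 rises and 168 falls (176 and 146 with library totals) and lay -0.00056 from drawn genes (permutation, adjusted p = 0.978); without siDHX37 replicate 1 the difference was 0.038 (adjusted p = 0.0455). For all siNC super-enhancers the difference was 0.035 (permutation, adjusted p = 0.00261), and it was not past the threshold without siNC replicate 1 (0.024, adjusted p = 0.0701), with unmatched genes (0.022, adjusted p = 0.118) or with all genes within 50 kb (0.011, adjusted p = 0.411).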

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

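The tests in this part were chosen after the result was seen, except the one that left out the 10 highest regions of each list.

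Summits outside chromosomes 1 to 22, X and Y were used in no comparison and numbered 74 in the siNC H3K27ac list, 71 in the siDHX37 H3K27ac list, 789 in the DHX37 list and 369 in the PLRG1 list, or 0.128%, 0.121%, 7.17% and 4.57% of each. Of these, 413 DHX37 and 238 PLRG1 summits lay on alternate contigs, which the H3K27ac lists do not name. On 2 contigs that hold copies of ribosomal DNA lay 44 DHX37, 18 PLRG1, 9 siNC H3K27ac and 8 siDHX37 H3K27ac summits.

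DHX37 and PLRG1 summits coincided more often than chance placed them. Active chromatin marked in general is argued against as the whole source: 66.4% of DHX37-bound H3K27ac summits had a PLRG1 summit, against 26.0% (at most 27.4%) of drawn H3K27ac summits matched on gene ends and score. Places where reads pile up whatever the antibody stay open: away from gene ends and H3K27ac, 25.6% of DHX37 summits had a PLRG1 summit nearby, the lowest share of the 4 kinds of place, but 65.7% of PLRG1 summits had a DHX37 summit nearby, against 64.7% at H3K27ac away from gene ends, and of the 50 highest DHX37 summits 96% had a PLRG1 summit nearby and 4% had siNC H3K27ac nearby. Tagging of open chromatin whatever the antibody stays open too, because no control-antibody library was used here; a DHX37 summit lay at 38.3% of gene-end H3K27ac summits in the highest score group and 14.9% in the lowest. A shared complex of DHX37 and PLRG1 on chromatin may also account for the pattern and was not tested.

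The description of siDHX37 replicate 1 names DHX34 as the target. A library made with an siRNA against DHX34 and not DHX37 is argued against: DHX37 was at 0.313 and DHX34 at 1.13 times the siNC mean in it. An error in the description alone stays open and was not tested.

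The siDHX37 list held fewer super-enhancers than the siNC list, 901 against 1306. The few highest regions set the scale of the cutoff and may account for this: the siNC number was 0.960 times the siDHX37 number without the 10 highest regions, which met the bound set in advance, but 1.27, 1.38, 1.251, 1.11, 1.103 and 1.14 times without the 1, 2, 5, 20, 50 and 100 highest, so this stays open. Scores lower by a common factor over the whole siDHX37 list could not change the number called, since each curve is scaled to its own highest region. Scores lower by unequal factors stay open. Ranking by number of summits gave 1.31 with whole-number cutoffs that differed between the lists. It gave 0.895 at more than 5 summits in both, a reading set after the result was seen. Nearest genes of regions called with siNC only were not lower as a group, at -0.00056 from drawn genes (two-sided permutation, adjusted p = 0.978). That is the outcome predicted without a loss of enhancer activity that lowers the nearest genes. A median near 0 over genes that went both ways cannot exclude such a loss at some regions, so it stays open there. With 1 library per list these explanations cannot be told apart.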

How the results depend on the processing

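Alternatives added after seeing the data were library totals, protein-coding gene ends, CUT&Tag summits near or away from H3K27ac, leaving out the highest regions (10 with its bound set before its result, the other numbers after it), the RNA alternatives of the super-enhancer gene comparison and its unmatched genes; the others, with the comparisons and the rule for named genes, were chosen before the data were examined. Of the alternative values that answer a comparison, 155 were the same in direction, side of the threshold or size, 45 moved, 11 reversed and 8 lost their call; of the others 1697 were the same, 8 moved, 9 reversed, 48 lost and 1 gained a call. The DHX37 fall, the odds ratios of a DHX37 or PLRG1 summit in siNC super-enhancers and the rise of the nearest genes of regions called with siDHX37 only kept their calls under each alternative run for them (unmatched odds ratios from 2.83 to 6.37 for DHX37 and from 2.497 to 5.23 for PLRG1; length-matched ones over the same settings from 1.43 to 2.08 and from 1.31 to 2.28). For each change below the cause was not tested.

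RNA calls were 2021 higher and 2379 lower with DESeq2, and 418 and 389 with a 2-fold minimum, against 3415 and 3680. With library totals 3937 rose and 3172 fell. Leaving out a library gave 2567 to 3094 higher and 2954 to 3398 lower genes; the group left with a lone library was assumed to vary like the other. With the replicate number as a block, 3405 rose and 3687 fell; the labels share only a number, and deviations of same-numbered libraries had a correlation of 0.061. Camera called 10 lists, 0 with an estimated correlation (2 at an unadjusted p under 0.05), and fry called 23. Among the lists lost with an estimated correlation, heat shock and cholesterol synthesis had estimates of -0.028 and -0.036, below the preset 0.01. The other lists called by camera had estimates above 0.01, from 0.0136 for liver transcription factors to 0.357 for G1/S genes. The 60S and 40S lists had 0.211 and 0.279, and the 40S list was not called by fry (adjusted p = 0.0792). Genes with no call changed sign as follows: MAN1A1 to 0.0264 with library totals and to 0.0227 without siDHX37 replicate 1 and 0.0328 without siNC replicate 2 (leave-one-out range -0.068 to 0.0328), MTND1P23 to 0.00642 and RALY to 0.0222 with library totals, RALY to 0.00266 without siDHX37 replicate 2 (leave-one-out range -0.048 to 0.00266), FAM86JP to -0.216 without siNC replicate 1 (-0.216 to 0.474), LINC00094 to -0.0318 without siNC replicate 2 (-0.0318 to 0.249) and LOC399900 to -0.639 without siDHX37 replicate 1 (-0.639 to 0.642).

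Summit sharing, siNC with siDHX37 and the reverse, was 50.9% and 50.5% within 200 bp, 75.4% and 81.2% within 1000 bp, and 71.6% for siDHX37 at scores of at least 10. DHX37 with PLRG1 and the reverse gave 44.6% and 59.2% within 200 bp, 58.6% and 77.7% within 1000 bp, 66.4% and 67.0% with equal numbers, 71.5% and 78.4% near H3K27ac and 41.1% and 71.5% away from it. DHX37 and PLRG1 with siNC H3K27ac gave 27.5% and 33.2% within 200 bp and 61.1% and 74.2% within 1000 bp. Chance by drawn H3K27ac summits was 19.8% and 24.7%, against 0.319% and 0.421% by shifts.

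Super-enhancers numbered 500 in each list by the top 500 regions, 1464 with siDHX37 when all summits were kept, and 1623, 1670, 2201 and 2373 with siDHX37 without the 10, 20, 50 and 100 highest regions; siNC had 2427 and 2704 without the 50 and 100 highest. The share of siNC super-enhancers that overlapped a siDHX37 one was 51.5% with 5 kb stitching, 63.9% with all summits, 63.3% with protein-coding ends and 64.4% for the top 500; the reverse was 64.3%, 75.8%, 74.1% and 64.2%, and 70.5% by number of summits.

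Differences from drawn genes for DHX37-bound genes were 0.0124 unmatched (permutation, adjusted p = 0.0729) and, with H3K27ac at an end, 0.00408, 0.00623 for PLRG1 and 0.00855 for both. For a DHX37 summit alone they were -0.00434 unmatched and -0.0154 with H3K27ac, and for PLRG1 alone -0.00462 and -0.00705. Nearest genes of siNC super-enhancers gave 0.0107 within 50 kb, 0.0222 unmatched and 0.0236 to 0.0463 in leave-one-out fits, and those called in both lists 0.0285 within 50 kb and 0.0355 to 0.0769 in leave-one-out fits. For regions called with siNC only the values were 0.0058 with DESeq2, 0.00263 with no filter, 0.00714 with the replicate block and 0.000385 to 0.0378 in leave-one-out fits (adjusted p = 0.0455 by permutation without siDHX37 replicate 1).

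One summit per peak was not run, since each entry is 1 summit. The RNA library with the fewest counts, siDHX37 replicate 2, had 9586863; how far depth limits the calls was not tested.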

Other observations

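The comparisons in this part were all chosen after the data were seen. Here the genes were drawn, matched on expression, from the 7297 with an H3K27ac summit at an end in both lists. Genes with an H3K27ac summit at an end in siNC cells only, 841 in number, had 174 rises and 267 falls. Their median log2 fold change lay 0.092 below that of drawn genes (two-sided permutation, adjusted p = 0.000183). Genes with such a summit in siDHX37 cells only, 733 in number, had 225 rises and 147 falls and lay 0.054 above drawn genes (two-sided permutation, adjusted p = 0.000629).

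DHX37 and PLRG1 summits at gene ends went with expression level: from the lowest to the highest of 10 expression groups, the bound share ran from 15.5% to 63.0% for DHX37 and from 13.2% to 59.4% for PLRG1. Among the gene lists, shares with a summit were compared with binomial draws at the bound share of other genes of like expression. These draws treat list members as independent. Over 108 tests, adjusted p = 0.0475 (binomial draws) for each pair that passed. Hepatocyte secreted proteins had fewer summits, with DHX37 at 29.0% of 31 genes against 54.1% and PLRG1 at 25.8% against 50.5%. DHX37 summits lay at 93.3% of 15 nonsense-mediated decay factors against 53.2% and at 81.8% of 11 replication-dependent histone genes against 37.9%. The PLRG1 shares, 80.0% and 45.5%, did not pass (binomial draws, adjusted p = 0.111 and 0.889). PLRG1 summits lay at 69.6% of 46 small subunit processome genes against 48.2% and at 80.6% of 31 spliceosome genes against 53.7%. The DHX37 shares, 65.2% and 80.6%, did not pass (binomial draws, adjusted p = 0.352 and 0.0839). Shares with both summits passed for processome (63.0% against 41.1%) and spliceosome genes (74.2% against 46.2%). They also passed for decay factors (80.0% against 42.4%) and secreted proteins (16.1% against 43.7%), but not for histone genes (45.5% against 29.1%). A difference between the DHX37 and PLRG1 shares of a list was not tested.

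The 50 highest DHX37 summits lay within 200 kb of a chromosome end in 34% of cases and near siNC H3K27ac in 4%; for PLRG1 the shares were 20% and 36%.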
